A study of Mus musculus with 16 samples.

How the data were processed

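Cells labelled by the red fluorescent protein tdTomato, a reporter of parvalbumin interneurons, were taken from the cortex and the dorsal striatum of mice aged 30 days. They were sorted by fluorescence-activated cell sorting (FACS). The labels give the strain as C57BL/6J and all mice as male. In one line the reporter was PV-tdTomato without Cre; in the other, PVCre;tdTomato, the Cre recombinase was expressed under parvalbumin control and switched the reporter on. Each replicate held 2000 cells pooled from 2 to 4 mice. Per the labels' protocols, total RNA was isolated with Trizol, 5 ng was amplified, and 5.5 µg of the resulting cDNA was labelled for an Affymetrix Mouse Transcriptome Array. There were 16 arrays, 4 in each combination of line and region.

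The authors deposited log2 expression values made by RMA, a procedure of background correction, normalization and probe set summary, in Affymetrix Expression Console, per the submitters' processing notes. The version of that software and the grouping of arrays during normalization are not given in the sources used here. The deposited table had 72688 probe sets, of which 6732 were control probe sets and 65956 were transcript clusters. Platform annotation gave 30888 clusters a single gene, 1862 several genes and listed no gene for 33206. Symbols of 827 clusters were updated through their Entrez gene number. Only clusters with a single gene were used. For the 355 genes with more than 1 such cluster, the cluster with the highest mean over all arrays stood for the gene. The third of the 30426 genes with the lowest mean (33.3%, a mean log2 level under 5.53) was left out, and 20284 genes were tested. No array was left out and no 2 arrays held identical values.

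Array medians lay between 5.97 and 6.13, and single values between 2.58 and 19.92. The 23 antigenomic background probe sets had mean levels of 2.95 to 6.1, so genes near or under 6 on the log2 scale were close to background. Microarrays give no read depth, and the number of arrays limits the precision. As a measure of array quality, the median level of the 1324 positive control probe sets minus that of the 5222 negative ones was computed for each array. The labels give no batch, slide or date, so a batch that followed the line cannot be told apart from the line.

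Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 16 arrays in 1 fit), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were striatum minus cortex over both lines and in each line, PVCre minus PV-tdTomato in each region, and the difference between the lines' region effects (interaction). Errors of differences are standard errors (SE); errors of levels are standard deviations (SD) over 4 arrays. Replicates were pools of sorted cells; the sources used here do not say whether a cortical and a striatal pool came from the same mice, and p-values measure the spread between these pools. In all, 16 gene lists and 8 lists of cell type markers were tested with limma's camera at its preset correlation, adjusted over the 24 lists, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

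Genes were named by a rule: for the region effect, the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap in either line; for each line effect, the 8 largest rises and 8 largest falls without overlap; for the interaction, the 5 largest in each direction. Up to 4 members of each list with the smallest p were added, and Pvalb, Gdnf, Gad1, Th, Xist and Y-linked genes were always included. Predicted models and clones were not named by rank. Groups, comparisons, lists, this rule and the first set of alternatives were fixed before the data were examined. These alternatives were other filters, every named probe set, quantile normalization, centring on array medians, a trended robust prior, array weights, fits on only the arrays compared, the replicate number as a block, a random block by description number, a minimum difference of 1 on the log2 scale, glial and vascular marker levels as a covariate, and each array left out in turn. Further alternatives were chosen after the data were seen: leaving out the 6 arrays with the lowest Pvalb level, Xist and Y-linked genes as covariates, and the control separation as a covariate.

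Replicate numbers in the titles are shared by the groups. After group means were removed, same-numbered PV-tdTomato arrays of the 2 regions correlated at r = 0.58 to 0.76 across genes in all 4 pairs, so these numbers were taken as pairs. In 2 of the 4 pairs the best match was the array's own number: replicates 1 and 2 both matched 1, and replicates 3 and 4 both matched 3. A likeness of replicates 1 and 2, and of 3 and 4, can give these correlations, so the pairs are an assumption. The other comparisons did not pass the check on correlations. In the PVCre cortex group, the numbers in the titles and in the descriptions differ.

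The fits were tested on simulated data with the arrays' own spread and 200 changed genes per comparison among 20284. Of the 50 genes changed by 1 on the log2 scale, 86% were recovered for the region effect over both lines, 52% and 54% in the PV-tdTomato and PVCre lines, 38% for the interaction, and 58% and 50% for the line effect in striatum and cortex. False calls numbered 4 to 10 per comparison. In simulated line effects in striatum, camera called all 24 lists shifted by 1 and 0 of 526 unshifted list tests. Simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.88. The simulation therefore does not show how often camera at its preset correlation calls lists falsely in these data. The block by description number used statmod 1.5.0. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.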

Results

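Cells with a tdTomato reporter of parvalbumin, a calcium-binding protein of fast-spiking interneurons, were sorted from mouse cortex and dorsal striatum. Their RNA was measured on 16 arrays. Mice of a PV-tdTomato line, in which the reporter was made without Cre, gave 4 striatal and 4 cortical arrays. Mice of a PVCre;tdTomato line, in which Cre expressed by parvalbumin cells switched the reporter on, gave 4 arrays of each region. Each array held the RNA of 2000 sorted cells. Values are RMA levels on the log2 scale. The positive control probe sets lay 4.53 ± 0.25 (SD, n = 4) above the negative ones in the PV-tdTomato striatal arrays and 4.46 ± 0.26 in the cortical ones. In the PVCre line this separation was 3.46 ± 0.25 in striatum and 3.50 ± 0.35 in cortex. No PVCre array, at 3.08 to 3.93, reached the range of the PV-tdTomato arrays, 4.16 to 4.85.

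Pvalb, the gene that defines the sorted cells, differed widely between replicates. Its level was 9.73 ± 2.23 (SD, n = 4) in PV-tdTomato striatum, 9.36 ± 2.68 in PV-tdTomato cortex, 11.24 ± 0.74 in PVCre striatum and 9.42 ± 2.6 in PVCre cortex. It lay between 6.69 and 8.40 in 6 arrays: replicates 3 and 4 of both PV-tdTomato groups and replicates 2 and 4 of PVCre cortex. The other 10 arrays lay between 10.20 and 12.48. Whether the 6 arrays hold mainly parvalbumin cells was not settled by Pvalb alone. Gad1, which encodes a GABA-synthesizing enzyme, was at 13.34 ± 1.09, 13.17 ± 0.99 and 13.42 ± 1.08 in PV-tdTomato striatum, PV-tdTomato cortex and PVCre striatum. In PVCre cortex it was at 10.39 ± 2.80, with 8.88 and 7.40 in replicates 2 and 4 and 11.63 and 13.66 in replicates 1 and 3. Gad2, another GABA synthesis gene, was at 6.79 and 6.56 in PVCre cortex replicates 2 and 4 and at 9.15 and 10.94 in replicates 1 and 3. The low levels in replicates 2 and 4 argue against mainly GABAergic cells there. In PV-tdTomato replicates 3 and 4, Gad1 stayed at 12.09 to 12.77. The mean level of the oligodendrocyte markers was between 11.46 and 12.09 in PV-tdTomato replicates 1 and 2 and between 13.74 and 14.18 in replicates 3 and 4. In PVCre it was 12.60 to 12.89 in striatum and 13.26 to 13.73 in cortex, with 13.68 and 13.73 in cortex replicates 2 and 4. The mean of these markers was thus far above background, which reached 6.1, in every array, those high in Pvalb included. The microglial markers averaged 5.63 ± 0.11 and 5.62 ± 0.24 in the PV-tdTomato groups, and 8.52 ± 0.58 and 8.75 ± 1.15 in PVCre striatum and cortex. The first principal component, with 55.1% of the variance, separated the lines. The second, with 21.7%, had negative values for PV-tdTomato replicates 3 and 4 and for PVCre cortex replicates 1, 2 and 4.

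**Figure D1:**
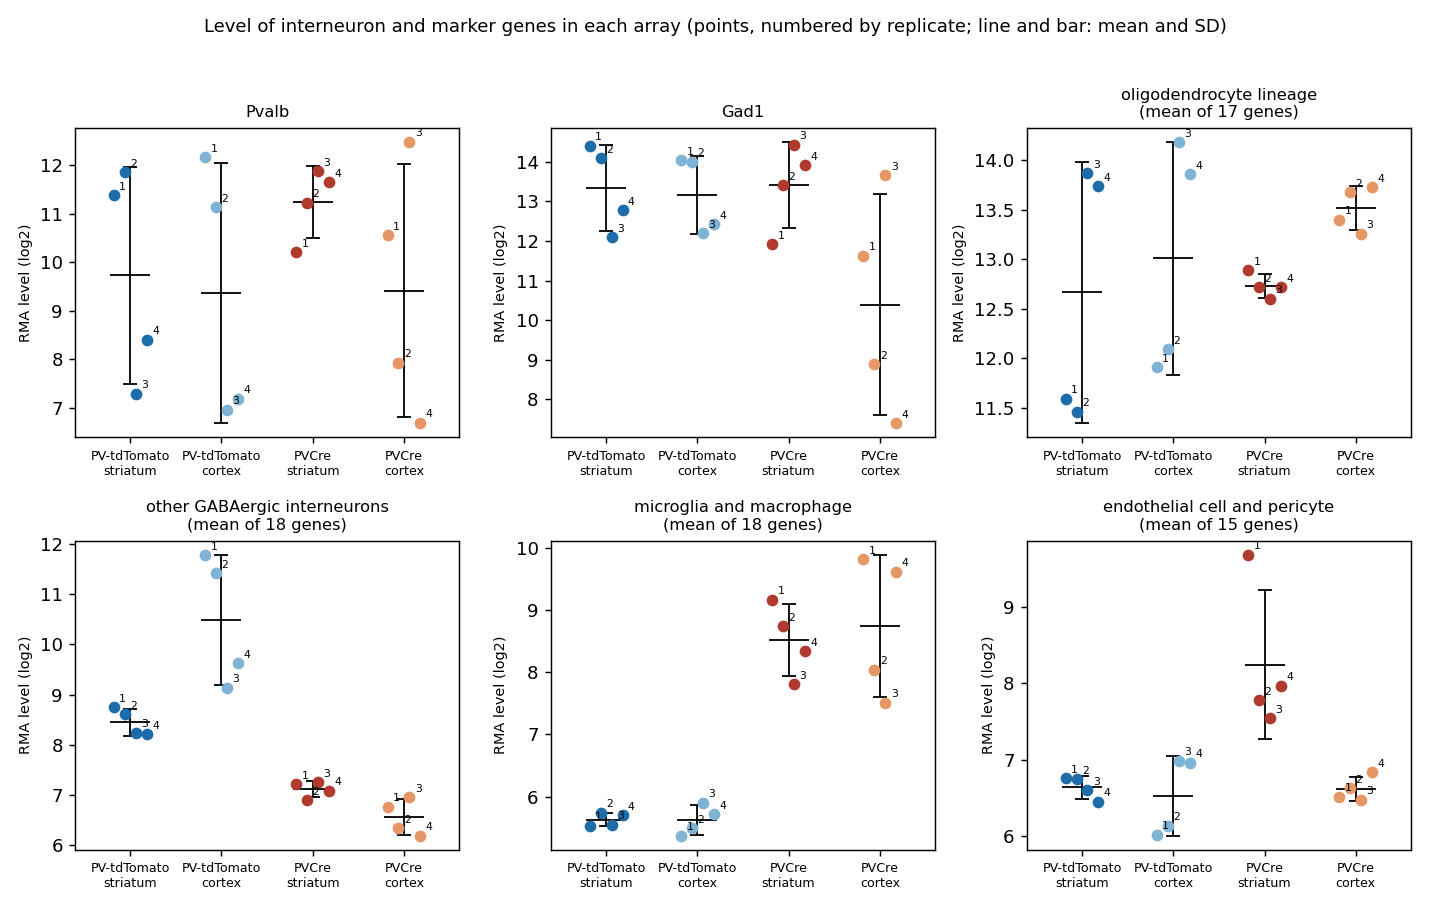
RMA levels (log2, vertical axis) of Pvalb and Gad1 and mean levels of the oligodendrocyte, other GABAergic, microglial and endothelial marker lists, by group (horizontal axis). Points are single arrays numbered by replicate, and lines with bars are the mean and SD of 4 arrays; the microglial mean is near 5.6 in both PV-tdTomato groups and above 8 in both PVCre groups.

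All mice were labelled male. Xist, the RNA that coats the inactive X chromosome of females, was above 12 in 8 of the 16 arrays and under 7 in the other 8. Replicate 3 of the PV-tdTomato line had Xist at 15.93 in striatum and 16.01 in cortex, with a mean level of 3 Y-linked genes of 5.93 and 6.10. The other PV-tdTomato arrays had Xist at 5.71 to 6.04 and Y-linked genes at 9.38 to 9.89. In the PVCre line, replicate 2 had Xist at 5.90 in striatum and 6.56 in cortex, and the other 6 arrays had it at 13.40 to 15.03. PVCre arrays with both signals included striatal replicates 1 and 4 and cortical replicate 4, with Y-linked genes at 7.50, 7.88 and 8.23. In each region high Xist was thus more frequent in PVCre than in PV-tdTomato arrays, so the comparisons between the lines include this difference.

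The first comparison asked how arrays of cells sorted from striatum and cortex differ. Over both lines, striatal arrays held more of Tmem212, a transmembrane protein gene, by 7.24 ± 0.27 (SE) on the log2 scale (limma adjusted p = 2.2e-09), with cortical levels of 5.88 and 6.15 close to background. Rsph4a, a radial spoke component of motile cilia, was higher by 5.32 ± 0.21, also from background in cortex (5.44 and 5.62), and Gpr83, a G protein-coupled receptor gene, by 6.04 ± 0.86 (65.7-fold). Crabp1, which binds retinoic acid, rose by 5.25 ± 0.53 (38.2-fold) and Il1rapl2, of the interleukin-1 receptor family, by 4.72 ± 0.51. Further rises were in Fam183b (5.61 ± 0.32), Mia (5.50 ± 0.40), Tm4sf1 (4.77 ± 0.24), Spata18 (4.62 ± 0.18) and Ccdc153 (4.40 ± 0.27). Cortical levels of Fam183b and Spata18 (5.34 to 5.63), of Tm4sf1 (5.69) and Il1rapl2 (6.05) in PV-tdTomato and of Mia (5.58) in PVCre were also within background, which reached 6.1, so the size and rank of these differences depend on it. The adjusted p of these 10 genes was 4e-04 or lower, and in each line no striatal array overlapped a cortical one, as the naming rule required.

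Among genes higher in cortex, Zfp804b, a zinc finger gene, fell by 2.40 ± 0.47 (SE, adjusted p = 0.006) in striatum, with striatal levels of 5.59 and 4.70. These were within background, as were the striatal levels of Nrn1 (6.04 and 5.35) and Cck (6.03 and 5.53) and that of Sel1l3 in PVCre (5.75), so the size and rank of these falls depend on it. Nrn1, which encodes neuritin, fell by 2.34 ± 0.37 (adjusted p = 0.001), although that call was lost when the 6 arrays with the lowest Pvalb level were left out. Cck, the cholecystokinin gene, fell by 1.47 ± 0.25 (adjusted p = 0.0017), and the kainate receptor gene Grik2 by 1.56 ± 0.23 (adjusted p = 0.00057). Nr2f1, a transcription factor of interneuron and cortical development, fell by 1.27 ± 0.19 (adjusted p = 0.00077). Sel1l3, Nt5dc3, Slitrk2, Fam163a and Nectin1 were lower by 1.24 to 1.83. Pvalb differed by 1.10 ± 1.01 (adjusted p = 0.61) and Gad1 by 1.60 ± 0.77 (adjusted p = 0.34), less than the spread between replicates allowed to be called. Th, which encodes the rate-limiting enzyme of dopamine synthesis, rose by 3.05 ± 0.50 (adjusted p = 0.0013). Its striatal and cortical levels were 12.6 ± 1.76 and 7.62 ± 1.22 (SD, n = 4) in PV-tdTomato. In PVCre they were 7.87 ± 0.27 and 6.74 ± 0.2, so the rise was far larger in PV-tdTomato, although the interaction of Th was not called. Gdnf, a neurotrophic factor of dopaminergic neurons, had mean levels of 4.26 to 5.85 and was under the filter; without a filter its difference was 0.99 ± 0.18 (adjusted p = 0.0046). Of the 20284 genes tested, 864 passed the threshold, 675 higher and 189 lower in striatum (78.1% higher, and 55.4% with the replicate block to 85.6% over the alternatives). Without the 6 arrays with the lowest Pvalb level, 1581 genes passed, 926 higher and 655 lower, and 703 of these were among the 864.

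**Figure D2:**
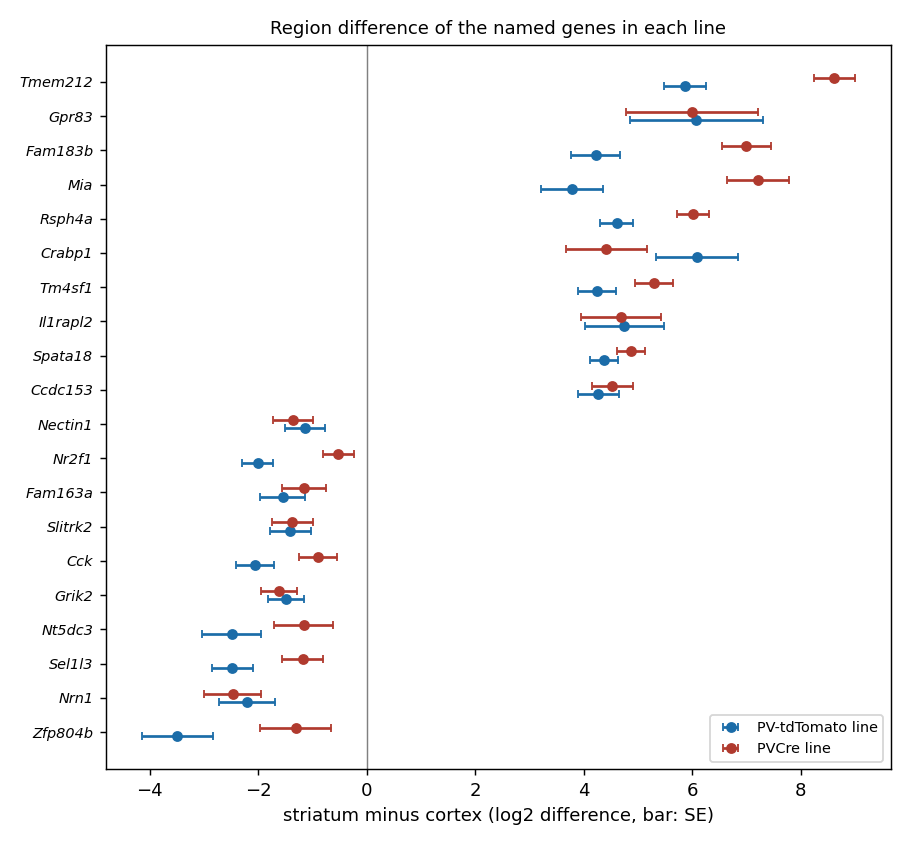
Striatum minus cortex (log2 difference, horizontal axis) of the 20 genes named by size of the region effect (vertical axis), in the PV-tdTomato and the PVCre line. Points are differences of group means of 4 arrays and bars are SE. Every gene has the same sign in both lines because the naming rule required it. Tmem212 is at the top of the rises, at 7.24 over both lines.

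Markers of striatal projection neurons, the principal cells of the striatum, were higher in striatal arrays: 12 of 23 rose and none fell (16 rose when adjusted over the list alone; camera adjusted p = 1.1e-16). This was the only list of the region effect over both lines whose call held with an estimated correlation (adjusted p = 0.041 with an estimated correlation). Rgs9 rose by 2.00 ± 0.22 (SE) and Ppp1r1b, which encodes DARPP-32, by 1.60 ± 0.17 (both adjusted p = 2.6e-05). Markers of other GABAergic interneurons were lower in striatal arrays, with 7 of 18 fallen and 1 risen (10 fallen and 3 risen adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.6 with an estimated correlation). They included Reln (-2.28 ± 0.32), Adarb2 (-2.62 ± 0.39), Ndnf (-1.88 ± 0.19) and Lamp5 (-1.12 ± 0.17), genes of neurogliaform and other cortical interneuron classes. The member that rose was Th. In the PVCre line alone, 1 of these markers rose and 0 fell. Of 17 cholesterol synthesis genes, 6 fell (16 adjusted over the list alone; adjusted p = 1.2e-12, and adjusted p = 0.32 with an estimated correlation), among them Hmgcs1 (-1 ± 0.24) and Fdps (-0.70 ± 0.16). Oligodendrocyte markers, cells that make much cholesterol for myelin, had a median difference of -0.51 with 0 of 17 called (0 adjusted over the list alone; adjusted p = 0.0024, and adjusted p = 0.72 with an estimated correlation).

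Endothelial and pericyte markers were higher in striatal arrays, with 3 of 15 risen (8 adjusted over the list alone; adjusted p = 3.5e-08, and adjusted p = 0.6 with an estimated correlation). Acta2, the smooth muscle actin gene, rose by 2.10 ± 0.24 (SE) and Pdgfrb by 0.97 ± 0.16. Of 13 astrocyte markers 4 rose, in either adjustment (4 adjusted over the list alone), including Sox9 (1.53 ± 0.18) and Mlc1 (1.83 ± 0.28). Their median difference was -0.01 while their mean was 0.51, and the test pointed up (adjusted p = 0.034, and adjusted p = 0.72 with an estimated correlation; 0.086 with the replicate block). Oxidative phosphorylation genes had a median difference of 0.38, with 0 of 69 called (0 adjusted over the list alone; adjusted p = 8.7e-09, and adjusted p = 0.72 with an estimated correlation). Cadherins and protocadherins, adhesion proteins, had 7 of 25 fallen and 4 risen (9 and 5 adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.6 with an estimated correlation; 0.094 with the replicate block). Pcdh10 fell by 1.02 ± 0.18, while Cdh13 rose by 1.46 ± 0.31.

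The remaining 16 lists did not pass the list test over both lines, but members of several did. Among the 23 PV interneuron identity genes, Nxph1, a neurexin ligand gene, rose by 2.34 ± 0.45 (SE, adjusted p = 0.0054), Satb1 fell by 1.03 ± 0.22 (adjusted p = 0.011), and the rest were not called (list adjusted p = 0.44; 3 risen and 2 fallen adjusted over the list alone). Of 27 forebrain interneuron transcription factors, 6 rose and 3 fell (10 and 6 adjusted over the list alone, list adjusted p = 0.15). Lhx8, which specifies ventral forebrain interneurons, rose by 2.59 ± 0.34, Meis2 by 1.45 ± 0.25 and Zic1 by 1.03 ± 0.14. Potassium channel genes Kcnab1 (2.90 ± 0.53) and Kcna4 (1.94 ± 0.31) were among 5 of 47 that rose, against 2 that fell (6 and 4 adjusted over the list alone, list adjusted p = 0.6). The AMPA receptor subunit Gria4 rose by 1.79 ± 0.34 and was the only riser of 20 glutamate receptors, with Grik2 the only one fallen (3 and 2 adjusted over the list alone, list adjusted p = 0.58). Gabra2, a GABA-A receptor subunit, rose by 2.25 ± 0.48 and was the only gene called of 13 (1 adjusted over the list alone, list adjusted p = 0.16).

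Of 38 neuromodulator receptors, 5 rose and 2 fell (7 and 5 adjusted over the list alone, list adjusted p = 0.6), with Drd2 higher by 1.84 ± 0.31 (SE). Of 51 axon guidance genes, 3 rose and 2 fell (4 and 4 adjusted over the list alone, list adjusted p = 0.66), with Epha4 higher by 2.06 ± 0.33. Adamts5 (2.96 ± 0.37), Hapln1 (2.89 ± 0.46) and Crtac1 (2.45 ± 0.46) were the members called of 23 perineuronal net and matrix genes (3 adjusted over the list alone, list adjusted p = 0.94). Syt10 rose by 2.46 ± 0.26 among 39 synaptic vesicle genes, of which 2 rose and 2 fell in either adjustment (2 and 2 adjusted over the list alone, list adjusted p = 0.44). Sodium and calcium channels had 1 of 27 risen and 2 fallen (1 and 3 adjusted over the list alone, list adjusted p = 0.37). Neurotrophic factors and receptors had 0 of 29 called by limma, against 864 of all 20284 genes (3 risen and 3 fallen adjusted over the list alone, list adjusted p = 0.23). Of all genes, 3112 had an unadjusted p under 0.05. Immediate early genes had 1 of 28 risen (1 risen and 1 fallen adjusted over the list alone, list adjusted p = 0.9), and heat shock genes 1 of 20 (2 adjusted over the list alone, list adjusted p = 0.15). Cholinergic markers had 1 of 5 risen and 1 fallen (2 and 1 adjusted over the list alone, list adjusted p = 0.21), and pyramidal neuron markers 2 of 17 risen and 2 fallen (3 and 4 adjusted over the list alone, list adjusted p = 0.11). Of the microglial markers 0 of 18 were called (0 adjusted over the list alone, list adjusted p = 0.36).

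In the PV-tdTomato line alone 472 genes passed, 351 higher and 121 lower in striatum, and in the PVCre line 791, with 580 higher and 211 lower (73.3% higher, and 52.8% with the replicate block to 83.9% over the alternatives). The counts were 1033 and 705 without the 6 arrays. Across genes, the region differences of the lines correlated with Pearson r = 0.52 and Spearman rho = 0.40, where genes are not independent replicates and the lines share no array. Both lines called 270 genes, 268 of them with the same sign. Markers of striatal projection neurons rose in both lines, 6 of 23 in PV-tdTomato and 8 of 23 in PVCre (11 and 16 adjusted over the list alone), with adjusted p = 0.044 and 0.12 with an estimated correlation. The PV-tdTomato list had 3 risen and an adjusted p of 0.061 without the 6 arrays. In PV-tdTomato 9 of 18 markers of other GABAergic interneurons fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 1.4e-16, and adjusted p = 0.079 with an estimated correlation). Npy, a neuropeptide gene, averaged 17.16 ± 0.31 (SD, n = 4) in PV-tdTomato cortex and 13.28 ± 1.26 in striatum. In PVCre 1 of these markers rose and none fell (4 and 0 adjusted over the list alone). Neurotrophic factors and receptors were lower in PV-tdTomato striatum (adjusted p = 0.00021, and adjusted p = 0.044 with an estimated correlation), with 1 risen and 1 fallen (1 and 7 adjusted over the list alone).

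In PVCre arrays, endothelial and pericyte markers were higher in striatum by a median of 1.55, with 8 of 15 risen (14 adjusted over the list alone; adjusted p = 3.2e-13, and adjusted p = 0.25 with an estimated correlation), against -0.02 in PV-tdTomato (1 risen, 3 adjusted over the list alone). PVCre striatum replicate 1 stood apart, with a mean of 9.68 against 7.54 to 7.97 in the other 3 arrays. Cholesterol synthesis genes fell in 8 of 17 cases in PVCre (17 adjusted over the list alone; adjusted p = 2e-13, and adjusted p = 0.25 with an estimated correlation), with Fdps, of the mevalonate pathway, at -1.22 ± 0.23 (SE). In PV-tdTomato none of the 17 was called (0 adjusted over the list alone), while the list had a median of -0.37 (adjusted p = 0.00019, and adjusted p = 0.88 with an estimated correlation). Oxidative phosphorylation genes had medians of 0.32 in PV-tdTomato and 0.47 in PVCre (adjusted p = 0.00019 and 1.9e-07; adjusted p = 0.9 and 0.74 with an estimated correlation) with 0 of 69 called in each. Astrocyte markers (3 of 13 risen), synaptic vesicle genes (3 of 39), interneuron transcription factors (1 of 27 risen, 1 fallen), GABA and glycine receptors (1 of 13) and potassium and HCN channels (5 of 47 risen, 1 fallen) also passed the list test in PVCre, at adjusted p of 0.0066 to 0.045. None of these 5 lists passed with an estimated correlation (adjusted p = 0.39 to 0.74 with an estimated correlation). Oligodendrocyte markers were lower in PVCre striatum (median -0.76, 0 of 17 called, adjusted p = 0.0033, and adjusted p = 0.74 with an estimated correlation). With the replicate block, oligodendrocyte markers were lower in PV-tdTomato striatum too at adjusted p = 1e-05, against 0.12 without it and adjusted p = 0.9 with an estimated correlation. Cadherins and protocadherins passed there without the block (adjusted p = 0.039, and adjusted p = 0.57 with an estimated correlation) and not with it (0.078).

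The second comparison set PVCre against PV-tdTomato arrays of striatum. Il1a, an interleukin gene, was higher by 10.29 ± 0.90 (SE, limma adjusted p = 8.7e-07) in PVCre, with levels of 4.67 ± 0.05 (SD, n = 4), within the range of background, and 14.96 ± 1.51. The chemokine gene Ccl3 rose by 8.88 ± 0.84, Tnf by 5.64 ± 0.92, and Tyrobp, Tlr7 and C3ar1, receptors or adaptors of myeloid cells, by 5.65 to 5.70. Bcl2a1a, which has near-identical paralogs that its probes may not separate, was higher by 9.79 ± 0.94. The PV-tdTomato levels of all these genes, 4.67 to 5.77, were within background. The probe set listed for Traj55, a joining segment of the T cell receptor alpha locus, rose by 7.84 ± 0.26 from 8.99 ± 0.52 to 16.83 ± 0.22 (SD), and which transcript it detects was not tested.

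Lower in PVCre striatum were Tacr3, the neurokinin B receptor gene (-5.09 ± 0.38, SE), Trh, the thyrotropin-releasing hormone gene (-5.00 ± 0.58), Th (-4.72 ± 0.70) and Calb2, the calretinin gene (-4.58 ± 0.63). Tnr (-5.09 ± 0.83), Bmp4 (-4.76 ± 0.93), Kcnip3 (-4.64 ± 0.67) and Lhfpl3 (-4.61 ± 0.85) were further large falls. Tacr3, Trh, Calb2 and Bmp4 were within background in PVCre striatum, at 5.15 to 5.99. The adjusted p of these 8 genes was 0.00067 or lower, and in none of them did the groups overlap, as the naming rule required. Pvalb differed by 1.51 ± 1.43 (adjusted p = 0.39) and Gad1 by 0.08 ± 1.08 (adjusted p = 0.96). Of all genes, 10820 passed, 3704 higher and 7116 lower (34.2% higher), and after quantile normalization 9631 passed, 4754 higher and 4877 lower (49.4% higher). The median difference of all genes was -0.23, and -0.02 after quantile normalization; list tests compare a list with all other genes. Leaving out the 6 arrays gave 11370 genes. These counts cover any batch or array quality that followed the line, since the control separations of the lines did not overlap. They also cover the difference in Xist and Y-linked levels, since high Xist was more frequent in the PVCre arrays. With these genes as covariates 9 lists passed camera in striatum, as many as without them.

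All 18 microglial and macrophage markers rose in PVCre striatum (18 adjusted over the list alone), by a median of 2.73 (adjusted p = 9.8e-11, and adjusted p = 0.37 with an estimated correlation). Ctss rose by 4.96 ± 0.60 (SE) and Cd68 by 3.23 ± 0.39. Of 28 immediate early genes, which are induced by stimulation and by handling of cells, 20 rose and 1 fell (20 and 2 adjusted over the list alone; adjusted p = 9.8e-11, and adjusted p = 0.37 with an estimated correlation). Atf3 rose by 4.64 ± 0.33, Zfp36 by 3.10 ± 0.25 and Egr3 by 1.51 ± 0.12. Endothelial and pericyte markers rose in 11 of 15 cases and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 4e-05, and adjusted p = 0.53 with an estimated correlation), with Ly6c1 higher by 3.67 ± 0.57. The mean of these markers was 9.68 in PVCre striatum replicate 1 and 7.54 to 7.97 in the other 3 arrays, and without that array the list adjusted p was 1e-05. Heat shock genes had 7 of 20 risen and 4 fallen (7 and 4 adjusted over the list alone, list adjusted p = 0.11), with Ddit3, a gene of the unfolded protein response, higher by 2.80 ± 0.39.

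Beside these rises of microglial, immediate early and endothelial genes, 6 lists of neuronal function were lower in PVCre striatum. Of 27 sodium and calcium channel genes 19 fell (20 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.73 with an estimated correlation), with Cacna1e at -3.05 ± 0.20 (SE). Of 20 glutamate receptors 13 fell (13 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.37 with an estimated correlation), with Grik3 at -3.44 ± 0.19. Axon guidance genes fell in 30 of 51 cases (30 adjusted over the list alone; adjusted p = 0.0022), and cadherins and protocadherins in 14 of 25 (15 adjusted over the list alone; adjusted p = 0.0097), both with adjusted p = 0.37 with an estimated correlation. Synaptic vesicle genes fell in 23 of 39 cases (23 adjusted over the list alone; adjusted p = 0.0051) and potassium and HCN channels in 22 of 47, with 1 risen (22 and 1 adjusted over the list alone; adjusted p = 0.028), both with adjusted p = 0.74 with an estimated correlation. The call of the channels ended when any of 3 arrays was left out. The median difference of the last 2 lists turned from -1.13 to 0.02 and from -0.92 to 0.39 with the control separation as a covariate, an alternative chosen after the data were seen. Glial and vascular markers as a covariate, fixed before, left them at -0.36 and -0.08, and the list tests pointed up (adjusted p = 0.98 and 0.41). PV interneuron identity genes fell in 3 of 23 cases (3 adjusted over the list alone, list adjusted p = 0.97), among them Slc32a1, the vesicular GABA transporter gene (-3.16 ± 0.94), and Lhx6 (-1.53 ± 0.48). Their median of -0.61 turned to 1.15 with glial and vascular markers (list adjusted p = 0.0024) and to 2.24 with the control separation (list adjusted p = 0.00041) as covariates.

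Other lists did not pass the list test in PVCre striatum, although many members fell. Neuromodulator receptors had 17 of 38 fallen and 1 risen (17 and 1 adjusted over the list alone, list adjusted p = 0.052), with the serotonin receptor gene Htr2c at -4.13 ± 0.73 (SE). Neurotrophic genes had 15 of 29 fallen and 1 risen (15 and 1 adjusted over the list alone, list adjusted p = 0.13), with Gfra2, a neurturin receptor gene, at -3.74 ± 0.38. Matrix genes had 12 of 23 fallen and 2 risen (12 and 2 adjusted over the list alone, list adjusted p = 0.11), and GABA and glycine receptors 5 of 13 fallen (5 adjusted over the list alone, list adjusted p = 0.15). Forebrain interneuron transcription factors had 6 of 27 fallen and 2 risen (6 and 1 adjusted over the list alone, list adjusted p = 0.97). Markers of striatal projection neurons fell in 11 of 23 cases (11 adjusted over the list alone, list adjusted p = 0.11), of other GABAergic interneurons in 6 of 18 (6 adjusted over the list alone, list adjusted p = 0.22) and of cholinergic interneurons in 3 of 5 (3 adjusted over the list alone, list adjusted p = 0.23). Pyramidal neuron markers had 9 of 17 fallen and 2 risen (10 and 2 adjusted over the list alone, list adjusted p = 0.22), and astrocyte markers 3 of 13 fallen (2 adjusted over the list alone, list adjusted p = 0.45). Oligodendrocyte markers had 5 of 17 risen, among them Mal and Cnp, and 3 fallen (5 and 3 adjusted over the list alone, list adjusted p = 0.21). Cholesterol synthesis genes had 6 of 17 risen and 6 fallen (6 and 7 adjusted over the list alone, list adjusted p = 0.6), and oxidative phosphorylation genes 7 of 69 risen and 10 fallen (4 and 5 adjusted over the list alone, list adjusted p = 0.22).

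The third comparison set PVCre against PV-tdTomato arrays of cortex. Genes of other interneuron classes were far lower in PVCre cortex. Cxcl14 was lower by 7.67 ± 0.56 (SE, limma adjusted p = 2.6e-07), with levels of 14.11 ± 1.59 (SD, n = 4) in PV-tdTomato and 6.44 ± 0.40, near background, in PVCre. The vasoactive intestinal peptide gene Vip differed by -7.25 ± 0.90, the serotonin receptor gene Htr3a by -6.42 ± 0.79, Npy by -6.41 ± 1.30 and Adarb2 by -6.94 ± 0.55, all known from interneurons other than parvalbumin cells. Tnfaip8l3 (-6.37 ± 0.50), Rab3c (-6.27 ± 0.93) and Sema3c (-6.09 ± 0.61) were further large falls. In PVCre cortex Vip, Adarb2, Htr3a, Tnfaip8l3 and Sema3c were at 5.65 to 5.81, within background, so the size of these differences depends on it. Of 18 markers of other GABAergic interneurons 15 fell (16 adjusted over the list alone), by a median of -4.38 (adjusted p = 1.7e-05, and adjusted p = 0.36 with an estimated correlation).

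The rises in PVCre cortex were led by the same 8 genes as in striatum, among them Il1a (9.45 ± 0.90, SE, from background at 4.79), Ccl3 (8.55 ± 0.84), Traj55 (7.75 ± 0.26), Tlr7 (6.03 ± 0.75) and Tnf (5.14 ± 0.92). Bcl2a1a, Tyrobp and C3ar1 rose by 9.07, 5.65 and 5.39. All of them but Traj55 were within background in PV-tdTomato cortex, at 4.75 to 5.74. All 18 microglial markers rose (18 adjusted over the list alone), by a median of 3.12 (adjusted p = 3.7e-11, and adjusted p = 0.24 with an estimated correlation), and 20 of 28 immediate early genes rose while 2 fell (21 and 2 adjusted over the list alone; adjusted p = 2.7e-10, and adjusted p = 0.21 with an estimated correlation). Atf3 was higher by 4.83 ± 0.33. Oligodendrocyte markers had 8 of 17 risen and 2 fallen (8 and 2 adjusted over the list alone; adjusted p = 0.03, and adjusted p = 0.69 with an estimated correlation), a call that ended when any of 3 arrays was left out. Cnp, a myelin enzyme gene, rose by 2.11 ± 0.34 and Cspg4, a gene of oligodendrocyte precursors, fell by 4.08 ± 1.01. The list's median was 0.91, and -0.13 with the control separation as a covariate. Of 17 cholesterol synthesis genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0047, and adjusted p = 0.55 with an estimated correlation), with Idi1 higher by 2.14 ± 0.32.

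Neuronal function genes were lower in PVCre cortex beside these glial rises. GABA and glycine receptors averaged 7.54 and 7.58 in PVCre cortex replicates 2 and 4, and 8.75 and 9.64 in replicates 1 and 3. Synaptic vesicle genes were at 7.29 and 7.2 against 7.99 and 8.38, and potassium and HCN channels at 7.08 and 7.04 against 7.79 and 8.26. The falls were thus larger in replicates 2 and 4, which were low in Pvalb and Gad1. Replicates 1 and 3 still lay under PV-tdTomato cortex, whose lowest arrays were at 9.98, 8.89 and 8.47 for these lists. GABA and glycine receptors fell in 11 of 13 cases (12 adjusted over the list alone; adjusted p = 0.0047), synaptic vesicle genes in 30 of 39 (30 adjusted over the list alone; adjusted p = 4.7e-05) and potassium and HCN channels in 30 of 47, with 1 risen (33 and 1 adjusted over the list alone; adjusted p = 0.00011), each with adjusted p = 0.53 with an estimated correlation. Glutamate receptors fell in 18 of 20 cases (19 adjusted over the list alone; adjusted p = 8.3e-05), axon guidance genes in 28 of 51 (28 adjusted over the list alone; adjusted p = 0.00073) and neurotrophic genes in 19 of 29, with 1 risen (21 and 1 adjusted over the list alone; adjusted p = 0.0044), each with adjusted p = 0.21 with an estimated correlation. Sodium and calcium channels fell in 21 of 27 cases with 1 risen (21 and 1 adjusted over the list alone; adjusted p = 0.00021, and adjusted p = 0.52 with an estimated correlation). Neuromodulator receptors fell in 20 of 38 cases (20 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.56 with an estimated correlation).

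Cadherins and protocadherins fell in 16 of 25 cases in PVCre cortex (16 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.24 with an estimated correlation), with Pcdh20 at -3.21 ± 0.26 (SE). Matrix genes fell in 14 of 23 cases with 1 risen (16 and 1 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation). Striatal projection neuron markers fell in 11 of 23 cases with 1 risen (11 and 1 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.55 with an estimated correlation), a call that ended when any of 7 arrays was left out. Forebrain interneuron transcription factors had 9 of 27 fallen and 2 risen (8 and 2 adjusted over the list alone, list adjusted p = 0.58). Oxidative phosphorylation genes had 12 of 69 fallen and 6 risen (8 and 3 adjusted over the list alone, list adjusted p = 0.69), heat shock genes 7 of 20 risen and 3 fallen (7 and 3 adjusted over the list alone, list adjusted p = 0.27), and pyramidal neuron markers 9 of 17 fallen and 2 risen (9 and 2 adjusted over the list alone, list adjusted p = 0.4). Cholinergic markers fell in 3 of 5 cases (3 adjusted over the list alone, list adjusted p = 0.19) and astrocyte markers in 6 of 13, with Aldoc among them (6 adjusted over the list alone, list adjusted p = 0.088). Endothelial and pericyte markers had 2 of 15 risen and 1 fallen (2 and 1 adjusted over the list alone, list adjusted p = 0.31), with Pecam1, an endothelial adhesion gene, higher by 1.52 ± 0.39.

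The glutamate receptor gene Grin3a (-4.39 ± 0.28, SE), Cplx2, a regulator of vesicle fusion (-4.64 ± 0.65), Kcnc4 (-3.66 ± 0.37) and Ptprz1 (-5.94 ± 0.89) fell in PVCre cortex. Gad2, a GABA synthesis gene (-4.54 ± 0.82), and Slc32a1 (-4.82 ± 0.94) were among 9 of 23 PV identity genes that fell (3 adjusted over the list alone, list adjusted p = 0.31). With the control separation as a covariate the median of this list turned from -1.18 to 1.09 (list adjusted p = 0.018). Gad1 was lower by 2.78 ± 1.08 (adjusted p = 0.043), a call that ended when any of 8 arrays was left out, and its difference turned to 0.89 with the control separation as a covariate. It was at 8.88 and 7.40 in PVCre cortex replicates 2 and 4, the arrays low in Pvalb, and at 11.63 and 13.66 in replicates 1 and 3. In PV-tdTomato cortex it was at 12.2 to 14.04. Pvalb differed by 0.05 ± 1.43 (adjusted p = 0.98). The transcription factors Nr2f2 (-4.47 ± 0.62) and Npas1 (-2.96 ± 0.51), of interneurons from the caudal ganglionic eminence and other sources, fell, while Nkx2-1 rose by 0.89 ± 0.11. In all, 10851 genes passed, 3875 higher and 6976 lower (35.7% higher), and after quantile normalization 10114 passed, 5267 higher and 4847 lower (52.1% higher). The median of all genes was -0.22, and 0.02 after quantile normalization. Leaving out the 6 arrays gave 9395 genes. Across genes, the line differences in striatum and cortex correlated with r = 0.87 and rho = 0.88, and 8813 of the 8828 genes called in both regions had the same sign. These regions share no array, but their PV-tdTomato arrays were taken as pairs, so the line differences are not independent and r has no value for no change beside it.

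**Figure D3:**
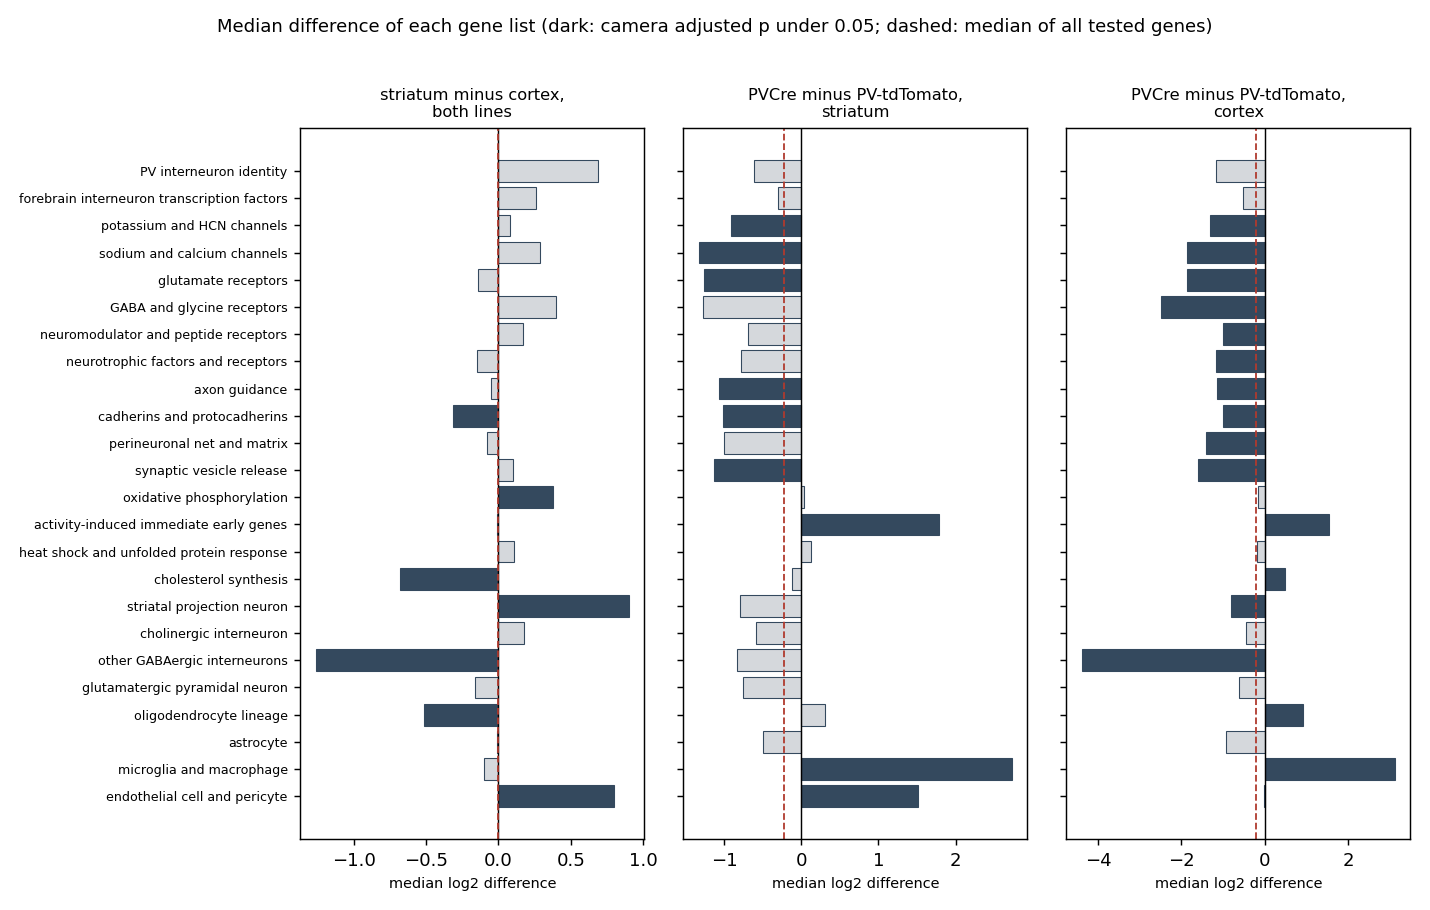
Median log2 difference (horizontal axis) of each of the 24 gene and marker lists (vertical axis) for striatum minus cortex over both lines, and for PVCre minus PV-tdTomato in striatum and in cortex. Dark bars passed the camera test at its preset correlation and dashed lines are the median of all tested genes; the microglial list is at 2.73 and 3.12 in the line effects and at -0.10 in the region effect.

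The last comparison tested whether the region effect differed between the lines, and 40 genes passed, 30 with a higher striatum-to-cortex difference in PVCre and 10 with a lower one. With the 6 arrays left out 153 passed, 27 of them among the 40. Ndnf (3.56 ± 0.38, SE, limma adjusted p = 0.0018), Cxcl14 (5.79 ± 0.79, adjusted p = 0.0075), Reln (4.20 ± 0.63, adjusted p = 0.016) and Adarb2 (4.96 ± 0.78, adjusted p = 0.016), genes of cortical interneurons, were higher in cortex than striatum in PV-tdTomato arrays, by more than in PVCre arrays. Vip had an interaction of 6.80 ± 1.27 (adjusted p = 0.049), from a mean of 13.06 in PV-tdTomato cortex against 5.18 to 5.81 in the other groups. Those levels were within background. Tacr3 (-4.05 ± 0.54, adjusted p = 0.0063) and Trh (-5.01 ± 0.82, adjusted p = 0.022) differed the other way. Fgfr1, a growth factor receptor gene, had 1.39 ± 0.18 (adjusted p = 0.0063). In PVCre striatum and cortex the levels of Ndnf, Reln, Adarb2, Tacr3, Trh and Mc3r, at 5.15 to 5.98, were also within background, as were those of Nr2f2 in PV-tdTomato striatum (5.65) and PVCre cortex (5.29), so the size and rank of these interactions depend on it. The calls of Vip, Gfra2, Necab1, Nr2f2, Cemip2, Mc3r and Trh ended when any of 15, 13, 12, 12, 10, 9 and 7 of the 16 arrays was left out.

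Of 18 markers of other GABAergic interneurons, 5 had a positive interaction (11, and 1 negative, adjusted over the list alone), with a median of 3.17 (adjusted p = 2.1e-18, and adjusted p = 0.087 with an estimated correlation). Endothelial and pericyte markers had a median of 1.25 with 0 of 15 called by limma (8 adjusted over the list alone; adjusted p = 4.3e-12, and adjusted p = 0.31 with an estimated correlation), and without PVCre striatum replicate 1, the highest array in these markers, the adjusted p was 5.7e-12. Beside these, cholesterol synthesis genes had a median of -0.69 with 0 of 17 called (1 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.62 with an estimated correlation), and neurotrophic genes 0.22, with Fgfr1 positive and Gfra2 negative (4 and 1 adjusted over the list alone; adjusted p = 0.00029, and adjusted p = 0.083 with an estimated correlation). In all genes, 1450 had an unadjusted p under 0.05. The other 8 lists past the preset threshold, at adjusted p of 0.00029 to 0.041, all had adjusted p = 0.8 with an estimated correlation. They covered PV identity, potassium, sodium and calcium channels, glutamate, GABA and neuromodulator receptors, synaptic vesicle genes and astrocyte markers. The remaining 12 lists had adjusted p of 0.057 to 0.87.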

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

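The tests on other splits of the arrays and on array quality for the interneuron genes were chosen after the results were seen; the other tests here were written before their values were seen, on gene lists drawn up after the top-ranked genes were known and without those genes, and the settings with control separation and without 6 arrays were also chosen after the data were seen.

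Microglial and cytokine genes were higher in PVCre arrays of both regions, and a candidate explanation is that microglial cells were among the cells sorted from this line. All 18 markers of the microglial list had already risen in both regions, so further microglial genes were likely to rise as well. A rise of such genes goes with this explanation but does not separate it from those left open below. Of a further list of 27 tested microglial genes, none in another list, 25 were higher in PVCre striatum (92.6%) and 26 in PVCre cortex (96.3%). The most abundant of them, Ly86, averaged 11.30 and 10.43 in PVCre striatum and cortex against 5.74 and 5.82 in PV-tdTomato, Plek 10.26 and 10.10 against 6.25 and 6.21, and Apbb1ip 7.76 and 7.98 against 6.92 and 7.78; a FACS gate on tdTomato that excluded autofluorescent or CD11b-positive cells would remove such cells. With the control separation as a covariate, 78.2% or more of the median of the microglial list was left in each region. Calls of the further list dropped to 11 and 14 of 27, and its medians fell from 2.53 to 1.58 and from 2.24 to 1.74. The control separations of the lines did not overlap, so this covariate was fitted on the spread within groups. It cannot decide whether array quality that followed the line was the cause, which stays open. A response of microglia or other cells to Cre or the reporter, and a batch that followed the line, also stay open and were not tested.

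Genes of other interneuron classes were higher in PV-tdTomato than in PVCre cortex arrays, and a candidate explanation is that such cells were among those sorted from the PV-tdTomato line. Of a further list of 21 tested genes of caudal interneurons, 17 were lower in PVCre cortex (81%). Of these 21, 8 were also in another list, where some of their values had been seen, and of the other 13, 9 were lower (69.2%). Of all 20284 genes, limma called 10851 in cortex in either direction, with a median of -0.22. Levels in PV-tdTomato and PVCre cortex were 13.30 and 9.85 for Kit, 12.78 and 11.87 for Prox1, 12.78 and 7.42 for Crh, 11.05 and 11.03 for Id2, and 9.96 and 9.95 for Zfp536, and a stricter FACS gate on bright tdTomato cells would remove cells with weak reporter expression. The median of the marker list was -4.50 without the 6 arrays and -4.38 with them. That setting also drops PV-tdTomato cortex replicates 3 and 4, so it does not isolate the PVCre arrays. The mean of the list was 6.19 to 6.96 in all PVCre cortex arrays, low in Pvalb or not, against 9.14 to 11.77 in PV-tdTomato cortex. These means argue against a shortage of interneurons in the PVCre cortex arrays low in Pvalb as the whole cause. With the control separation as a covariate, 80.4% of the main median was left. The list adjusted p was 4.3e-10 to 0.36 over all alternatives, the highest with an estimated correlation. In the further list only 7 of 21 genes (33.3%) stayed lower with that covariate, and the median went from -2.96 to -1.99. Since the control separations of the lines did not overlap, the covariate cannot decide on array quality. Array quality, the cells that each reporter labels and a batch that followed the line stay open.

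Other splits of the same arrays were counted for each set of called genes. For the line effect, 1 of 35 splits, the real one, gave as many as 10820 genes in striatum and 1 of 35 as many as 10851 in cortex. The highest other split gave 1 and 13 genes. This share is under 0.05 and the smallest that 35 splits can give, so it goes against chance without excluding it. For the region effect in the PVCre line the real split gave 791 genes and the highest other 140 (1 of 35), the same share. In the PV-tdTomato line the real split gave 472 genes, but the split of replicates 1 and 2 against 3 and 4 across regions gave 4971 (2 of 35), so chance was not excluded. That split points to a structure of the samples, the one seen in Pvalb and in oligodendrocyte markers. Of the 8 splits that part every pair of same-numbered arrays in this line, the highest other than the real one called 0 by limma, against 472 in the real split. In the real split 1616 genes had an unadjusted p under 0.05. These 8 splits are too few for a share under 0.05. Over both lines the real split gave 864 genes and the highest other 6204 (2 of 100), a share under 0.05, and such a split again points to a structure of the samples. Of 100 splits that part every same-numbered pair of PV-tdTomato arrays, 1 gave as many, and the highest other gave 336. For the interaction the real split gave 40 genes and the highest other 4555 (5 of 100), so chance was not excluded by splits that ignore the pairs. Of 100 splits that part every PV-tdTomato pair, 2 gave as many, with 54 in the highest other, a share under 0.05.

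Differences between the lines in the region effect drew attention in 10 named genes. The interaction was 6.80 for Vip, 5.91 for Necab1, 5.79 for Cxcl14, 5.18 for Nr2f2 and 4.96 for Adarb2, and it was -5.01 for Trh, -4.05 for Tacr3, -3.33 for Mc3r, -2.99 for Gfra2 and -2.33 for Cemip2. With Xist and Y-linked genes as covariates, the calls of Vip, Necab1, Nr2f2, Adarb2, Trh, Mc3r, Gfra2 and Cemip2 ended. Among lists, the median interaction was 3.17 for other GABAergic interneurons, 1.25 for endothelial cells and pericytes, 1.04 for GABA and glycine receptors, 0.61 for PV identity and 0.59 for glutamate receptors. It was 0.38 for potassium and HCN channels, 0.37 for synaptic vesicle release, 0.36 for astrocytes, 0.22 for neurotrophic factors and receptors, 0.21 for neuromodulator receptors and 0.18 for sodium and calcium channels. Cholesterol synthesis had -0.69. When the 6 arrays were left out, the list calls of PV identity (adjusted p = 0.94), GABA and glycine receptors (0.47), astrocytes (0.15) and cholesterol synthesis (0.062) ended.

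Single arrays lay far from the other 3 of their group in 16 of 332 combinations of measure and group, where a rate of 1 in 20 would give 16.6 by chance. Sex-linked genes made up 9 of the 16. Xist was at 15.93 in PV-tdTomato striatum replicate 3, 16.01 in PV-tdTomato cortex replicate 3, 5.90 in PVCre striatum replicate 2 and 6.56 in PVCre cortex replicate 2. In PV-tdTomato replicate 3, Kdm5d was at 5.90 in striatum and 5.78 in cortex, Uty at 6.15 in each, and Eif2s3y at 5.75 in striatum, against 9.54 to 9.98 in the other striatal arrays.

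PVCre striatum replicate 1 had the lowest control separation of its group, 3.09 against 3.56 to 3.6, a mean of oxidative phosphorylation genes of 11.66 against 12.09 to 12.14, and Tacr3 at 5.50 against 4.98 to 5.06. PV-tdTomato striatum replicate 3 had a mean of neurotrophic genes of 9.46 against 9.32 to 9.34. Gdnf was at 4.09 in PV-tdTomato cortex replicate 4 against 4.30 to 4.34, near background. Nt5dc3 was at 9.52 in PVCre cortex replicate 3 against 7.45 to 7.76, and Tnf at 5.76 in PV-tdTomato striatum replicate 1 against 5.20 to 5.28.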

How the results depend on the processing

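Alternatives with the sex genes or the control separation as covariates, and without the 6 arrays lowest in Pvalb, were chosen after the data were seen. The others were fixed before. No read depth applies; genes near background, such as Gdnf, and the 4 arrays of each group limit what could be called. Where a result changed, the cause was not tested, except that a minimum difference by construction calls fewer genes. Among the named genes, leaving out single arrays kept the side of the threshold in 1082 of 1168 cases and ended the call in 86. Other settings kept it in 1018 of 1058, ended 27 calls, added 12 and reversed 1. For genes and lists, direction was compared only where the main or the alternative fit called the result. A result called in neither counted as kept even if its sign changed. Among the lists, leaving out single arrays kept 1434 of 1536, ended 72 and added 30. Other settings kept 801 of 960, ended 89, added 58 and reversed 12. The kept cases include those of the trended robust prior by construction, because the list test did not use that prior. Array weights called 5647 genes for the region effect over both lines, 1632 in PV-tdTomato, 2488 in PVCre and 130 for the interaction, with r = 0.68 between the lines' region effects. The replicate block called 2061 over both lines, 578 in PV-tdTomato, 2081 in PVCre and 127 for the interaction. Numbers were taken as pairs only for the PV-tdTomato regions, where the block ended the call of cadherins and added that of oligodendrocyte markers. The random block called 1424, 1266 in PVCre and 102 for the interaction. A minimum difference of 1 left 383, 309 and 477 genes for the region effect over both lines, in PV-tdTomato and in PVCre, and 4573 and 4704 for the line effect in striatum and cortex. With glial and vascular markers as a covariate, 3549 genes over both lines, 4033 in PVCre and 461 for the interaction passed. In PV-tdTomato, the stricter filter on level gave 302 and using only the arrays compared 282. Without the 6 arrays, 1581 over both lines, 1033 in PV-tdTomato and 153 for the interaction passed. With the control separation, 1269 in PVCre and 5578 and 5373 for the line effect in striatum and cortex passed. With sex genes, 19 passed for the interaction. Lists called for the region effect over both lines numbered 8, and 13 without the 6 arrays. For the line effect in striatum they numbered 9, and 14 with no filter, with quantile normalization and without the 6 arrays, and 5 with the control separation. With an estimated correlation 1 list was called for the region effect over both lines, 0 of 9 and 0 of 16 for the line effect in striatum and cortex, and 0 of 12 for the interaction. Reversed lists were PV identity (adjusted p = 0.042) and potassium and HCN channels (0.01) for the region effect without the 6 arrays. In the striatal line effect PV identity, potassium and HCN channels and synaptic vesicle release reversed with glial markers (0.0024, 0.41, 0.98) and with the control separation (0.00041, 0.23, 0.56). In the cortical line effect PV identity (0.018) and oligodendrocyte markers (0.58) reversed with the control separation. In the interaction cholinergic markers (0.0082, stricter filter) and oxidative phosphorylation (4.7e-06, without the 6 arrays) reversed. Gad1 in the cortical line effect turned to 0.89 on the log2 scale with the control separation. Leaving out 1 array at a time gave 665 to 967 genes over both lines, 337 to 495 in PV-tdTomato, 510 (without PVCre cortex 2) to 820 in PVCre, 9771 to 10969 and 9760 to 10988 for the line effect in striatum and cortex, and 21 to 69 for the interaction. That last count was 26 and 23 without PV-tdTomato striatum 1 and 4, 22, 24 and 69 without PV-tdTomato cortex 1, 2 and 3, 23 and 25 without PVCre striatum 2 and 4, and 24, 22 and 21 without PVCre cortex 1, 2 and 4. The r between lines was 0.33 to 0.63: 0.40 and 0.37 without PV-tdTomato striatum 1 and 2, 0.63, 0.33 and 0.40 without PV-tdTomato cortex 2, 3 and 4. Lists called numbered 6 to 11 for the region effect over both lines (11 without PVCre cortex 3), 8 to 11 and 15 to 17 for the line effect in striatum and cortex, and 6 to 13 for the interaction: 6 and 7 without PV-tdTomato cortex 1 and 2, 6 without PVCre striatum 3, and 7 and 7 without PVCre cortex 2 and 4. For the region effect over both lines, cadherins were lost without PV-tdTomato cortex 1 (0.092) or 2 (0.097) or PVCre striatum 1 (0.14), and astrocyte markers without PV-tdTomato striatum 3 (0.15) or 4 (0.13), PV-tdTomato cortex 1 (0.13) or 2 (0.11), PVCre striatum 1 (0.099), or PVCre cortex 1 (0.064) or 3 (0.053). For the line effect in striatum, potassium and HCN channels were lost without PV-tdTomato striatum 1 (0.073) or 2 (0.06) or PVCre striatum 1 (0.097). For the line effect in cortex, oligodendrocyte markers were lost without PV-tdTomato cortex 1 (0.098) or 2 (0.078) or PVCre cortex 2 (0.058), and striatal projection neuron markers without PV-tdTomato striatum 3 (0.051), PV-tdTomato cortex 1 (0.098) or 2 (0.079), PVCre striatum 1 (0.059), 3 (0.05) or 4 (0.053), or PVCre cortex 4 (0.11). In the interaction, calls ended when single arrays were left out for astrocytes (10 arrays, 0.055 to 0.67), sodium and calcium channels (9, 0.07 to 0.43), glutamate receptors (9, 0.061 to 0.19), PV identity (8, 0.072 to 0.58), GABA and glycine (6, 0.076 to 0.14) and neuromodulator receptors (6, 0.067 to 0.43), and synaptic vesicle release (PV-tdTomato cortex 1, 0.073).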

Other observations

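The lists used here were drawn up after the top-ranked genes were known, without those genes; the tests on the cilia list were written before their values were seen, except that on array quality between regions, and the settings with control separation and without 6 arrays were chosen after the data were seen.

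Genes of oligodendrocyte precursors differed between the lines. Of a list of 22 tested genes, 14 were lower in PVCre striatum (63.6%) and 14 lower and 1 higher in PVCre cortex, with medians of -1.93 and -1.80. Of all 20284 genes, limma called 10820 in striatum and 10851 in cortex in either direction, with medians of -0.23 and -0.22. Sox8, a transcription factor of the oligodendrocyte lineage, averaged 13.03 and 13.34 in PV-tdTomato striatum and cortex and 10.91 and 11.42 in PVCre, and Sulf2 13.46 and 13.71 against 11.51 and 12.02. The most abundant member, Ugt8a, which is also expressed in myelinating cells, averaged 12.60 and 13 against 13.69 and 14.15. The mean of the list was 9.66 ± 1.39 and 9.96 ± 1.28 (SD, n = 4) in the PV-tdTomato groups and 8.04 ± 0.07 and 8.32 ± 0.25 in the PVCre groups. Within PV-tdTomato it was 10.56 to 11.21 in replicates 3 and 4 and 8.45 to 8.99 in replicates 1 and 2. Without the 6 arrays the medians were -0.63 and -0.89, with 5 genes higher and 13 lower in each region. They were -3.45 and -3.38 with the control separation, and -3.28 and -2.83 with glial and vascular markers, as covariates. Of the list, 6 genes, Vcan, Pcdh15, Cacng4, Olig1, Olig2 and Ugt8a, were also in another list.

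The level of the probe set listed for Traj55, a joining segment of the T cell receptor alpha locus, was 16.83 ± 0.22 and 16.96 ± 0.42 (SD, n = 4) in PVCre striatum and cortex, and 8.99 ± 0.52 and 9.20 ± 0.34 in PV-tdTomato. Whether it detects that segment, a transcript of a transgene or a repeat was not tested.

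Cilia genes such as Rsph4a were higher in striatal arrays of both lines, and a candidate explanation is that ependymal cells, which line the ventricle beside the striatum and bear motile cilia, were among the sorted cells. Of a further list of 34 tested motile cilia and ependymal genes, none of them in another list, 32 were higher in striatum over both lines (94.1%), 30 in PV-tdTomato and 32 in PVCre, with a median of 1.67. Among the most abundant, Enkur averaged 8.46 and 10.15 in PV-tdTomato and PVCre striatum against 5.83 and 6.27 in cortex, Cfap54 8.93 and 9.35 against 6.06 and 5.68, Dynlrb2 7.75 and 9.59 against 5.50 and 6.55, and Ccdc39 only 7.93 and 7.85 against 7.49 and 6.91, and a FACS gate on bright tdTomato cells or a dissection away from the ventricle would remove such cells. Array quality differing between the regions is argued against by the control separation, whose means differed by 0.07 and -0.04 between striatum and cortex in the PV-tdTomato and PVCre lines, less than the SD between replicates and in opposite directions, while the mean of the cilia list was 6.81 to 8.04 in the striatal and 5.55 to 6.03 in the cortical arrays. Expression of these genes in striatal interneurons themselves stays open, as does the make-up of the pools: the median was 1.66 with the control separation as a covariate, which bears on array quality alone, and a replicate block cannot move a difference between balanced regions.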
